A study of Rattus norvegicus with 141 samples.

How the data were processed

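Adult wild-type Sprague-Dawley rats of both sexes received vehicle or microplastics at 5 or 50 mg/kg, and liver, stomach and duodenum were taken for sequencing of polyadenylated RNA. Per the labels' protocols, several small frozen pieces of each tissue were ground together before extraction, and the mass of tissue varied. The labels give each library's tissue, sex, dose group, replicate number and batch (1 of 3).

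The values used were estimated counts per gene, which the authors deposited as 1 table per tissue and which need not be whole numbers. Per the submitters' processing notes, the tools included FastQC 0.12.1, MultiQC 1.28, UMI-tools 1.1.5, cutadapt 4.9, Trim Galore 0.6.10, STAR 2.7.11b and Salmon 1.10.3 with the genome build mRatBN7.2; their roles, order and settings, the annotation release and the strand setting are not given in the sources used here. UMI-tools works on molecular identifiers, but whether duplicates were removed is not given in the sources used here either. Each table held 30562 genes, 4380 of them without a symbol. Of the gene values 9.47% in liver, 11.3% in stomach and 11.9% in duodenum were fractional, and deposited expected counts at transcript level added up to the gene values within 1e-06. No pair of libraries held identical values, and the highest correlation between libraries of log2 CPM was 0.9955.

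The expected counts were rounded to whole numbers, which changed library totals by 0.00064% or less. Per tissue, genes were kept by filterByExpr of edgeR 4.0.16 (R 4.3.3) with a minimum count of 10 and a minimum total of 15, which left 13130 genes in liver, 15140 in stomach and 15189 in duodenum. Library sizes were scaled by TMM. A quasi-likelihood model (glmQLFit and glmQLFTest) had a term for each combination of sex and dose and a term for batch, over all libraries of the tissue. Contrasts compared each dose with control over both sexes and within each sex, high with low dose, the dose effects between sexes, and female with male controls. P-values were adjusted by Benjamini and Hochberg over the genes of a tissue, and an adjusted p under 0.05 counted as a call. Standard errors were taken from the edgeR fit. Values within a batch came from refits on batch 1 or batch 2 alone.

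In total 52 gene lists for pathways and cell types were fixed in advance and tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, wherever at least 5 members were measured: 37 lists in liver, 48 in stomach and 47 in duodenum. Camera compares the members of a list with all other genes, and its p was adjusted over the lists of a contrast. The test was repeated with the correlation estimated from the data. Genes named were, for each dose contrast, the 10 higher and the 10 lower with the smallest p among those called that have a symbol. Where fewer than 5 passed, the 5 with the smallest p were named with their values. For female against male controls the rule took 8 each way and members of the sex lists. For each list with a call or a called member up to 4 members with the smallest p were named, and 2 otherwise, and a few sentinel genes per tissue were named whatever their result. For brevity some genes that the rule would name are left out. Some genes that the rule names are not reported here. Shares of counts from gene classes were compared by two-sided permutation tests of 1e+05 resamples within batch and sex (or batch and dose), adjusted over 42 tests. Gene spans were matched by symbol to an annotation of the assembly GRCr8, for 12390 of 13130, 14177 of 15140 and 14073 of 15189 genes; no coordinates of it are given.

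Alternatives chosen before the data were examined were DESeq2 1.42.0, DESeq2's size factors within edgeR, no filter on low counts, no batch term, the replicate number as a block, 3 surrogate variables (sva 3.50.0), limma voom with quality weights and a fit of only the groups compared. Chosen after seeing the data were the ribosomal protein share and the small noncoding RNA share as covariates (294 and 415 genes), leaving out batch 3, leaving out each library in turn and, for duodenum, the mean of enterocyte markers as a covariate and leaving out male control replicate 1. Counts of calls were set against 100 splits of the same libraries within each contrast, the real one included, with dose labels permuted within sex, or sex labels among controls, and again with labels also kept in their batch. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

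The edgeR steps were tested on simulated data with the means and library sizes of the real libraries, in which 200 genes differed at the high dose. For the high dose over both sexes, 71 of 100 genes with a 1.5-fold change and 88 of 100 with a 2-fold change were recovered in liver (13130 genes), 81 and 95 in stomach (15140) and 69 and 88 in duodenum (15189). False calls made up 7.02%, 6.88% and 7.1% of the calls, no recovered gene had the wrong sign, and the unchanged low dose gave 0 calls in each tissue. Counting error alone is small for genes well above the filter at totals of 4947800 to 25504000 per library, so the precision of a change is set mainly by the spread between libraries.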

Results

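Polyadenylated RNA was sequenced from the liver, stomach and duodenum of adult male and female Sprague-Dawley rats. They had been fed standard chow and given vehicle or microplastics at a low (5 mg/kg) or high dose (50 mg/kg). The comparisons ask which transcripts differed at each dose and whether the sexes responded alike. The analysis covered 141 libraries, 46 from liver, 48 from stomach and 47 from duodenum. Each combination of sex, dose and tissue had 8 libraries, except the duodenum female controls with 7 and the liver high-dose females with 6. Total estimated counts per library ranged from 6153400 to 23717000 in liver, from 4947800 to 23940000 in stomach and from 5470000 to 25504000 in duodenum. Summed transcripts of Y-linked genes were at least 76.0 CPM (counts scaled to library size) in every library labelled male. They were at most 0.731 CPM in every library labelled female. The labels do not say which libraries came from separate animals, so the p-values measure the spread between these samples.

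Changes are given as log2 ratios ± SE from edgeR. A pair of values in square brackets gives the same change inside batch 1 and then inside batch 2. Genes were called over all batches together, so equal signs there are no separate evidence. Batch 3 held 0 to 2 libraries of each group and was not read alone. Lists of genes were tested with camera, and none of the list calls below held when the correlation between genes was estimated from the data instead of preset. That second adjusted p follows the first.

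Ribosomal protein genes, which encode the protein part of the ribosome, took a larger share of all counts at the high dose in both gut tissues. In stomach the mean share was 3.42 ± 1.12% (SD, n = 16) in controls, 3.92 ± 1.35% (n = 16) at the low dose and 5.15 ± 2.06% (n = 16) at the high dose. The high dose exceeded control by 1.89 percentage points within batch and sex [0.979, 2.78] (two-sided permutation p = 0.00186, adjusted p = 0.026 over 42 measures). In duodenum the share was 4.39 ± 0.768% (n = 15) in controls, 5.07 ± 0.948% (n = 16) at the low dose and 6.32 ± 1.72% (n = 16) at the high dose. The high-dose difference was 2.07 points [1.43, 2.73] (permutation p = 0.00029, adjusted p = 0.00609). The low-dose differences of 0.581 points in stomach (permutation p = 0.18) and 0.65 points in duodenum (permutation p = 0.0394, adjusted p = 0.239) did not pass. Liver shares were 1.65 ± 0.53%, 1.65 ± 0.712% and 1.71 ± 0.672% in the same order. The high-dose difference there, of 0.0118 points, did not pass (permutation p = 0.952).

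**Figure D1:**
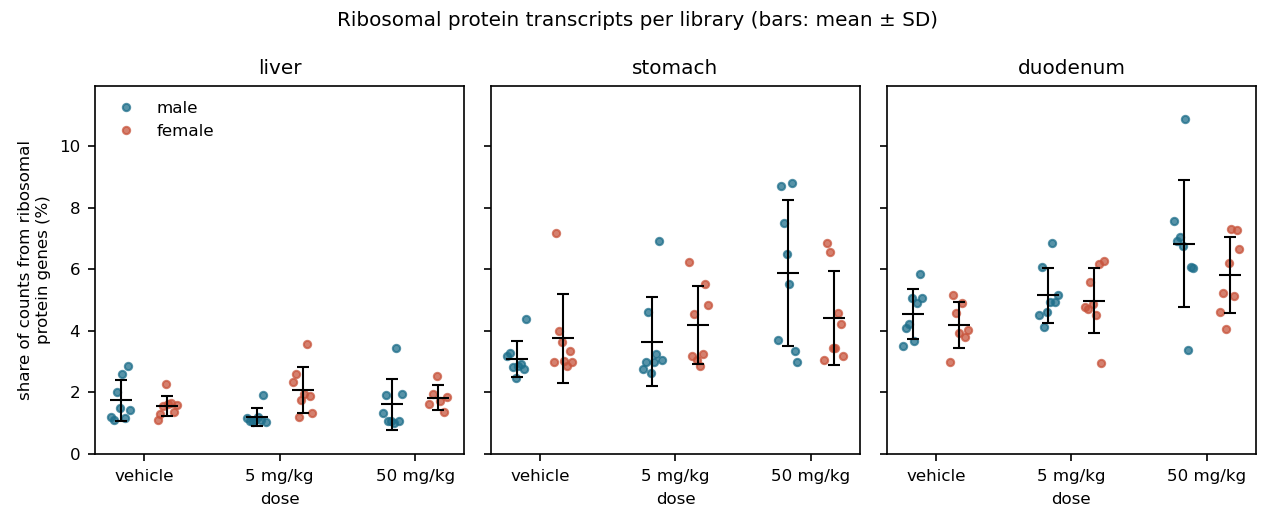
Share of counts from ribosomal protein genes in percent (vertical axis) per library, by dose, sex and tissue, with the mean ± SD of each group. Stomach and duodenum means over both sexes were 5.15% and 6.32% at the high dose against 3.42% and 4.39% in controls.

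At the high dose in stomach Defb14 and Defb1, which encode antimicrobial defensins, rose by 1.66 ± 0.30 [1.82, 1.57] and 1.08 ± 0.24 [1.11, 0.92]. Lyz2, the lysozyme of macrophages, rose by 0.51 ± 0.11 [0.44, 0.58]. Gpr34, a receptor of myeloid cells, rose by 0.65 ± 0.14 [0.71, 0.75], Trem2, a lipid-sensing receptor of macrophages, by 0.80 ± 0.18 [0.61, 0.98], and Rgs10, a regulator of G protein signalling, by 0.73 ± 0.13 [0.59, 0.90]. Among the 10 higher genes with the smallest p were also Stfa3, a stefin that inhibits cysteine proteases (1.09 ± 0.21 [1.04, 1.02]) and Hopx (0.76 ± 0.15 [0.72, 0.75]). The same group held Dbi, the acyl-CoA binding protein (0.79 ± 0.17 [0.68, 0.94]), Rbm3, a cold-inducible RNA-binding protein (0.45 ± 0.081 [0.37, 0.58]), and Nsa2, a ribosome assembly factor (0.35 ± 0.071 [0.30, 0.47]). With 3 surrogate variables Dbi turned to -0.018. The 10 lower genes with the smallest p included Mecom, a zinc finger transcription factor (-0.34 ± 0.062 [-0.45, -0.29]), Klhdc7a (-0.49 ± 0.10 [-0.50, -0.49]) and Uggt1, a folding sensor of the endoplasmic reticulum (-0.33 ± 0.072 [-0.34, -0.36]). Flt1, a receptor for VEGF (-0.28 ± 0.062 [-0.28, -0.29]), Extl3, an enzyme of heparan sulphate synthesis (-0.21 ± 0.046 [-0.20, -0.19]), and Mipep, a mitochondrial peptidase (-0.19 ± 0.041 [-0.23, -0.15]), also fell. The kinesin binding protein Kifbp (-0.26 ± 0.051 [-0.33, -0.24]) and the hydrolase Prepl (-0.25 ± 0.053 [-0.29, -0.25]) fell as well. The antimicrobial list was not called (camera adjusted p = 0.0746, and 0.454 with an estimated correlation), with 2 of 6 higher and 1 lower over all genes and 3 and 1 adjusted over the list alone. Hjv, a coreceptor for BMP, went from 1.83 ± 3.35 to 0.32 ± 0.501 CPM. The edgeR adjusted p of these genes ranged from 0.00872 to 0.0437.

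Ribosomal protein genes were the list with the smallest p in the high-dose stomach. Of 21 measured, 19 rose over all genes tested and 21 adjusted over the list alone, with a median of 0.46 (camera adjusted p = 1.31e-19, and 0.405 with an estimated correlation). Examples were Rps6 (0.56 ± 0.12 [0.49, 0.77]), Rpl28 (0.41 ± 0.084 [0.39, 0.53]), Rpl10a (0.46 ± 0.11 [0.44, 0.60]) and Rpl3 (0.28 ± 0.060 [0.22, 0.38]). Markers of parietal cells, which secrete gastric acid, had a lower median of -0.27 (camera adjusted p = 0.000364, and 0.626 with an estimated correlation). Of 12 parietal markers 2 fell, Esrrg (-0.34 ± 0.10 [-0.52, -0.22]) and the potassium channel Kcnj15 (-0.34 ± 0.10 [-0.66, -0.13]), and 8 fell adjusted over the list alone. Cell cycle genes were also lower as a list, with a median of -0.15 (camera adjusted p = 0.00166, and 0.663 with an estimated correlation). Of 22, 1 fell over all genes, the topoisomerase Top2a (-0.36 ± 0.10 [-0.29, -0.47]), against 3 adjusted over the list alone. Cenpf was at -0.38 ± 0.12 [-0.23, -0.51] with edgeR adjusted p = 0.052.

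Some immune cell lists were higher in the same stomachs by the camera test, with few single members past the threshold. T and NK cell markers (median 0.30) and B and plasma cell markers (-0.094) were not called (camera adjusted p = 0.205 and 0.889). Macrophage markers had a median of 0.20 (camera adjusted p = 0.0159, and 0.663 with an estimated correlation). Of 11, 1 rose, Lyz2, against 4 adjusted over the list alone, and the female median was 0.037 (camera adjusted p = 0.718). Mast cell markers had a median of 0.42 (camera adjusted p = 0.00682, and 0.405 with an estimated correlation), with 0 of 7 past the edgeR threshold and 2 adjusted over the list alone. Fcer1a, the IgE receptor alpha chain (0.73 ± 0.23 [0.59, 0.91]), and Cma1, a chymase (0.42 ± 0.15 [0.29, 0.48]), had the smallest p. Genes of eosinophils and type 2 immunity had a median of 0.27 (camera adjusted p = 0.0123, and 0.405 with an estimated correlation), with 0 of 6 past the threshold and 3 adjusted over the list alone. The eotaxin receptor Ccr3 (0.69 ± 0.23 [0.77, 0.71]) and the chemokine Ccl24 (0.44 ± 0.15 [0.43, 0.52]) led it. MHC class II genes had a median of 0.17 (camera adjusted p = 0.024, and 0.663 with an estimated correlation). Smooth muscle markers had one of 0.13 (camera adjusted p = 0.0372, and 0.89 with an estimated correlation). Neither of these lists had a member past the threshold, over all genes or adjusted over the list alone. Among lists without a call, the tight junction proteins Tjp3 (-0.22 ± 0.062 [-0.23, -0.18]) and Cgn (-0.24 ± 0.069 [-0.14, -0.33]) fell, as did the polymeric immunoglobulin receptor Pigr (-0.30 ± 0.090 [-0.19, -0.39]; 0.048 with 3 surrogate variables). Ebp, an enzyme of cholesterol synthesis, rose (0.23 ± 0.064 [0.24, 0.23]). The proton pump gene Atp4a was at -0.29 ± 0.094 [-0.46, -0.15], the pepsinogen Pgc at -0.25 ± 0.16 [-0.27, -0.31], and the surface mucin Muc5ac at -0.42 ± 0.14 [-0.046, -0.66]. The gastrokine Gkn1 was at 0.20 ± 0.15 [0.10, 0.45] and Cyp1a1, a target of the aryl hydrocarbon receptor, at 0.49 ± 0.31 [0.14, 0.26], these 5 with edgeR adjusted p from 0.0567 to 0.429.

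Over both sexes, edgeR called 680 genes at the high dose in stomach, 401 higher and 279 lower, with 16 libraries a side and a median absolute log2 change of 0.37. Inside batch 1, 2 genes passed and inside batch 2 0. The count was 0 with 3 surrogate variables, 1 with the ribosomal protein share as a covariate and 4 without the batch term. Leaving out single libraries gave 4 (male high replicate 4) to 1465 (female control replicate 2), and 31 of 48 such counts stayed within 1.5 times. The labels describe homogenising equipment that was rinsed between samples of 1 treatment and taken apart for cleaning only between treatments. Tissue handling thus ran along with dose.

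**Figure D2:**
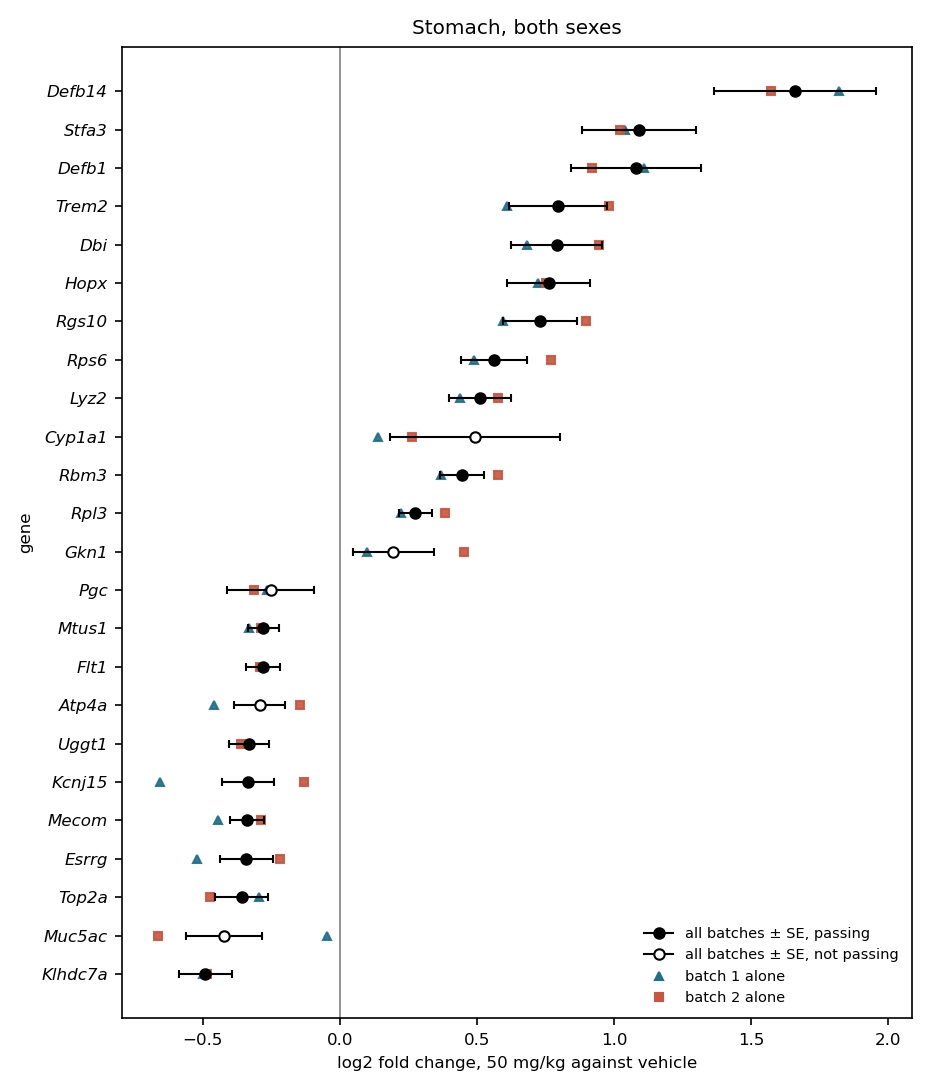
Log2 change ± SE at the high dose in stomach (horizontal axis) for named genes, pooled (circles) and within batch 1 (triangles) and batch 2 (squares); open circles did not pass the edgeR threshold. Defb14 stood at 1.66 ± 0.30 and Mecom at -0.34 ± 0.062.

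In males alone, the high-dose stomach had 19 of 21 ribosomal protein genes higher, 21 adjusted over the list alone, with a median of 0.70 (camera adjusted p = 5.88e-21, and 0.284 with an estimated correlation). Rps6 (0.88 ± 0.17 [0.81, 1.15]), Rpl14 (1.06 ± 0.22 [0.87, 1.47]) and Rpl4 (0.97 ± 0.20 [0.92, 1.29]) were among them. Also among the genes with the smallest p were Rgs10 (1.1 ± 0.19 [0.97, 1.33]) and Nsa2 (0.57 ± 0.10 [0.49, 0.76]). So were 4 ribosomal protein copies or pseudogenes, which can share reads with their parent genes and are not read. The lower genes with the smallest p included Prepl (-0.43 ± 0.074 [-0.48, -0.49]) and Mecom (-0.38 ± 0.087 [-0.57, -0.32]).

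Macrophage genes went up in these males: of 11 markers 4 rose, over all genes and adjusted over the list alone. The camera test passed (median 0.26, adjusted p = 0.00209, and 0.652 with an estimated correlation). The 4 were Lyz2 (0.70 ± 0.16 [0.66, 0.75]), the complement components C1qa (0.45 ± 0.14 [0.49, 0.45]) and C1qc (0.50 ± 0.14 [0.54, 0.51]), and Aif1 (0.54 ± 0.16 [0.20, 0.93]). Trem2 (1.04 ± 0.25 [1.3, 1.21]), the monocyte chemokine Ccl2 (0.97 ± 0.26 [0.84, 1.30]), Fcer1a (1.05 ± 0.30 [0.72, 1.36]), Ccr3 (1.1 ± 0.32 [1.17, 1.19]) and Ccl24 (0.64 ± 0.21 [0.76, 0.75]) rose as well. Antimicrobial genes had a median of 0.98 (camera adjusted p = 0.0178, and 0.284 with an estimated correlation). Of 6, 3 were higher, Defb1 (1.53 ± 0.34 [1.24, 1.58]), Lyz2 and the lectin Reg3b, which went from 0.601 ± 0.446 to 12.1 ± 28.9 CPM with a wide spread. Adjusted over the list alone 5 were higher and 1 lower. Parietal markers had a median of -0.29 (camera adjusted p = 0.024, and 0.822 with an estimated correlation). Of 12, 1 was lower, Esrrg (-0.44 ± 0.14 [-0.65, -0.37]), and 4 adjusted over the list alone. Cell cycle genes (camera adjusted p = 0.0178, and 0.822 with an estimated correlation), eosinophil genes (adjusted p = 0.0398, and 0.652 with an estimated correlation) and MHC class II genes (adjusted p = 0.0398, and 0.793 with an estimated correlation) passed too. They had 1, 2 and 1 members past the threshold and 0, 2 and 4 adjusted over the list alone, Top2a at -0.44 ± 0.14 [-0.57, -0.43] and RT1-Da at 0.43 ± 0.14 [0.57, 0.41]. Outside these lists, the respiratory chain subunits Cox7a2 (1.03 ± 0.29 [0.59, 1.64]), Ndufa4 (0.60 ± 0.18 [0.39, 0.95]) and Atp5po (0.61 ± 0.19 [0.39, 1.04]), the chaperonin Hspe1 (0.86 ± 0.25 [0.51, 1.36]) and the intestinal fatty acid binding protein Fabp2 (1.36 ± 0.37 [1.36, 2.17]) rose. The lipid synthesis genes Acacb (-0.47 ± 0.13 [-0.54, -0.47]) and Srebf1 (-0.33 ± 0.10 [-0.39, -0.29]) fell. With the ribosomal protein share as a covariate Cox7a2, Ndufa4, Atp5po, Hspe1 and Ccl2 turned negative, and with 3 surrogate variables Acacb turned positive, none passing.

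edgeR called 1069 genes in males, 749 higher and 320 lower (n = 8 a side). It called 0 in females (n = 8 a side), where 880 had an unadjusted p under 0.05, DESeq2 called 1 and voom 0. The female genes with the smallest p included Mipep (-0.25 ± 0.058 [-0.27, -0.18]), Kifbp (-0.29 ± 0.072 [-0.34, -0.25]) and Stt3b (-0.19 ± 0.049 [-0.15, -0.19]), at edgeR adjusted p from 0.539 to 0.848. In females 11 lists passed. Among them were ribosomal protein genes (median 0.22, camera adjusted p = 4.61e-06), parietal markers (-0.24, 2.57e-05), cholesterol synthesis (0.17, 2.57e-05) and forestomach squamous markers (0.33, 0.00341). All were at adjusted p = 0.695 with an estimated correlation, each with 0 members past the threshold and 0 adjusted over the list alone. Over all batches the sexes were not shown to differ gene by gene. The test of sex by dose called 0 genes with edgeR (857 unadjusted), 0 with DESeq2 and 0 with voom. Inside batch 1 edgeR called 10 for it and 3 for high-dose females, and 0 inside batch 2. Inside batches the male count was 7 and 0. It was 0 with the ribosomal protein share as a covariate, 0 with 3 surrogate variables and 3 without the batch term. It was 275 and 508 without male control replicates 4 and 2, 287, 329, 357 and 547 without male high replicates 4, 2, 3 and 6, and 1631 without male high replicate 7.

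Several genes separated the high-dose from the low-dose stomach. Stfa3 (1.18 ± 0.21 [1.12, 1.19]), Fam25a (1.18 ± 0.21 [1.07, 1.07]), Hopx (0.83 ± 0.15 [0.82, 0.85]), the serpin Serpinb11 (0.93 ± 0.18 [1.04, 0.76]) and Mt4, the metallothionein of stratified squamous epithelium (1.01 ± 0.20 [1.12, 0.88]), were higher at the high dose. Defb1 (1.26 ± 0.24 [1.15, 1.30]), Card9, an adaptor of antifungal signalling (0.33 ± 0.060 [0.36, 0.26]), and the casein kinase subunit Csnk2b (0.28 ± 0.050 [0.27, 0.29]) were higher too. Lower were Met, the receptor for hepatocyte growth factor (-0.27 ± 0.060 [-0.18, -0.30]), the integrin Itgb6 (-0.26 ± 0.061 [-0.35, -0.22]) and Extl3 (-0.18 ± 0.045 [-0.14, -0.20]). The squamous marker share of counts stood, on a log2 percent scale, at -0.10 ± 0.73 (SD, n = 16) at the low dose, 0.23 ± 0.63 (n = 16) in controls and 0.55 ± 0.57 (n = 16) at the high dose. It was not tested between the doses, and high minus control was 0.26 [0.55, -0.17] (permutation p = 0.264). edgeR called 107 genes, 93 higher and 14 lower, with adjusted p from 0.00453 to 0.0434 for those named. None passed inside batch 1 or batch 2 by edgeR (1185 and 1050 at unadjusted p under 0.05). The count was 0 without the batch term, 0 with 3 surrogate variables and 0 without batch 3. Leaving out single libraries gave 10 (female high replicate 1) to 421 (male low replicate 8), with 26 of 48 within 1.5 times.

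In the low-dose stomach the camera test called squamous forestomach markers lower and pancreatic acinar markers higher, while edgeR called 0 genes. The 15 squamous markers had a median of -0.34, all negative (camera adjusted p = 2e-07, and 0.698 with an estimated correlation), with 0 past the threshold and 2 adjusted over the list alone. The keratins Krt17 (-1.35 ± 0.35 [-1.72, -1.03]) and Krt13 (-0.57 ± 0.20 [-0.15, -0.79]) had the smallest p. The squamous share of counts differed from controls by -0.29 [0.14, -0.72] (permutation p = 0.302) on a log2 scale, and the acinar share by 0.33 [0.38, 0.33] (permutation p = 0.18), neither passing. The 12 acinar markers, which encode digestive enzymes of the pancreas, all had positive changes (camera adjusted p = 0.000558, and 0.721 with an estimated correlation), with 0 past the threshold and 5 adjusted over the list alone. Prss1, a trypsinogen, exceeded 100 CPM in 3 of 24 female and 0 of 24 male stomach libraries. The acinar share of counts reached 1.44% in female low replicate 7. Ribosomal protein genes were higher as a list (median 0.16, camera adjusted p = 1.41e-06, and 0.721 with an estimated correlation), as were adipocyte markers (0.44, adjusted p = 0.000558, and 0.698 with an estimated correlation) and MHC class II genes (0.15, adjusted p = 0.00208, and 0.698 with an estimated correlation), each with 0 members past the threshold and 0 adjusted over the list alone. The genes with the smallest p included Trdn (-1.58 ± 0.38 [-1.08, -1.69]) and C16h10orf71 (-1.31 ± 0.31 [-0.84, -1.65]), which are known from striated muscle. With them was the immunoglobulin segment Igkvl2, from 0.147 ± 0.54 to 2.31 ± 2.65 CPM, all at edgeR adjusted p from 0.425. Beside them, the striated muscle share of counts differed from controls by -1.25 log2 units [-1.0, -1.24] without passing (permutation p = 0.0438, adjusted p = 0.239).

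edgeR called 0 genes at the low dose in stomach over both sexes (909 at unadjusted p under 0.05), against 28 by DESeq2 and 0 by voom. In males the edgeR count was 0 (1041 unadjusted, 3 by DESeq2, 9 by voom), with 13 inside batch 1, all higher, and 0 inside batch 2. Krt17 came closest at -2.53 ± 0.49 [-2.65, -2.50] with edgeR adjusted p = 0.0951. In females it was 0 (435 unadjusted, 0 by DESeq2, 0 by voom).

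In duodenum ribosomal protein and cell cycle genes were higher and immediate early genes lower at the high dose. Of 21 ribosomal protein genes 17 rose, 21 adjusted over the list alone (median 0.47, camera adjusted p = 9.25e-14, and 0.838 with an estimated correlation). Among them were Rpl14 (0.67 ± 0.14 [0.37, 0.82]), Rps9 (0.60 ± 0.13 [0.35, 0.76]), Rpl11 (0.63 ± 0.14 [0.37, 0.81]) and Rpl4 (0.63 ± 0.14 [0.31, 0.87]). Of 22 cell cycle genes 9 rose, 10 adjusted over the list alone (median 0.17, camera adjusted p = 0.000362, and 0.838 with an estimated correlation). They included the survivin gene Birc5 (0.47 ± 0.10 [0.39, 0.53]), the cyclin-dependent kinase Cdk1 (0.36 ± 0.087 [0.34, 0.35]), the replication clamp Pcna (0.31 ± 0.078 [0.21, 0.38]) and the cyclin Ccnb1 (0.34 ± 0.093 [0.27, 0.41]). Respiratory chain genes of the nucleus had 4 of 20 higher, 10 adjusted over the list alone (median 0.25, camera adjusted p = 0.000196, and 0.843 with an estimated correlation). These were Ndufb5 (0.49 ± 0.15 [0.22, 0.56]), Cox7a2 (0.52 ± 0.16 [0.10, 0.69]), Atp5po (0.47 ± 0.15 [0.18, 0.64]) and Ndufa4 (0.48 ± 0.15 [0.24, 0.60]). With the ribosomal protein share as a covariate Cox7a2 and Ndufa4 turned negative without passing. Immediate early genes, which respond within minutes to stimuli, had 7 of 17 lower, 7 adjusted over the list alone (median -0.46, camera adjusted p = 0.000362, and 0.838 with an estimated correlation). Examples were Jun (-0.71 ± 0.18 [-0.50, -1.03]), Zfp36 (-0.65 ± 0.16 [-0.36, -0.97]), Btg2 (-0.39 ± 0.11 [-0.27, -0.60]) and Klf4 (-0.57 ± 0.16 [-0.53, -0.75]).

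Tight junction and barrier genes were lower as a list, and single members of the goblet and enterocyte lists fell. Tight junction and barrier genes had 5 of 13 lower, 6 adjusted over the list alone (median -0.23, camera adjusted p = 0.00613, and 0.838 with an estimated correlation). Among them were Tjp3 (-0.30 ± 0.074 [-0.18, -0.35]), the E-cadherin gene Cdh1 (-0.27 ± 0.069 [-0.22, -0.37]) and the claudin Cldn4 (-2.26 ± 0.59 [-1.95, -2.65]). Of the goblet list, the mucins Muc2 (-0.58 ± 0.18 [-0.41, -0.80]) and Muc13 (-0.71 ± 0.21 [-0.85, -0.88]) and Clca4 (-1.36 ± 0.45 [-1.42, -1.72]) fell. These were 3 of its 10 members, against 2 higher and 4 lower adjusted over the list alone. The lipoprotein gene Apob (-1.18 ± 0.37 [-1.25, -1.43]) was the 1 of 16 enterocyte markers to fall, over all genes and adjusted over the list alone. With 3 surrogate variables Muc2, Clca4 and Apob turned to 0.067, 0.12 and 0.023, and with the ribosomal protein share as a covariate Muc2 to 0.081, none passing. Neither list passed the camera test (adjusted p = 0.654 and 0.0829). The mean of the enterocyte markers was 9.36 ± 1.03 log2 CPM (SD, n = 15) in controls and 9.02 ± 0.693 (n = 16) at the high dose. The difference was -0.34 [-0.47, -0.17] (permutation p = 0.321). Fabp2, the intestinal fatty acid binding protein, was at -0.53 ± 0.35 [-1.11, -0.23], the alkaline phosphatase Alpi at -0.75 ± 0.32 [-1.0, -0.82] and the lectin Reg3g at -0.74 ± 0.48 [-0.14, -1.02], none passing (edgeR adjusted p from 0.102 to 0.311). Cyp1a1, a target of the aryl hydrocarbon receptor, fell from 35.1 ± 45.2 to 9.4 ± 6.85 CPM (-1.86 ± 0.54 [-2.56, -1.66]). Of 9 targets of the receptors CAR and PXR 4 fell, 6 adjusted over the list alone. The 4 were Cyp3a62 (-1.24 ± 0.38 [-1.19, -1.52]), Cyp2b1 (-1.03 ± 0.32 [-0.88, -1.26]), the transporter Abcc3 (-0.33 ± 0.10 [-0.21, -0.45]) and the reductase Por (-0.42 ± 0.14 [-0.40, -0.48]). That list missed the camera threshold (median -0.66, adjusted p = 0.0767). Ahrr, another target of the aryl hydrocarbon receptor, fell in the pooled test (-0.42 ± 0.14 [0.027, -0.59]) but was not lower in batch 1.

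The higher genes with the smallest p included Mtg1 (0.48 ± 0.089 [0.34, 0.54]) and Mrps10 (0.53 ± 0.11 [0.27, 0.68]), which serve mitochondrial ribosomes, and the nucleoporin Nup54 (0.33 ± 0.065 [0.26, 0.39]). Others were Pts, an enzyme of tetrahydrobiopterin synthesis (0.55 ± 0.11 [0.35, 0.66]), and the ubiquitin enzyme variant Ube2v2 (0.43 ± 0.089 [0.29, 0.61]). The lower ones included the transcriptional repressor Prdm1 (-0.68 ± 0.14 [-0.40, -1.04]), the RNA-editing enzyme Adar (-0.33 ± 0.067 [-0.22, -0.45]) and the laminin chain Lamb3 (-2.06 ± 0.42 [-1.64, -2.58]). With them was Ly6m, which went from 1.93 ± 3.1 to 0.103 ± 0.177 CPM. Of the interferon response genes 3 of 20 fell, Rsad2 (-1.90 ± 0.53 [-1.83, -2.20]), Oasl (-0.74 ± 0.23 [-0.72, -1.01]) and Stat2 (-0.22 ± 0.069 [-0.13, -0.29]). Of the circadian genes 3 of 17 fell, including Npas2 (-0.57 ± 0.15 [-0.52, -0.70]) and Nfil3 (-0.34 ± 0.11 [-0.14, -0.47]). Adjusted over the list alone 3 and 3 fell, with camera adjusted p = 0.315 and 0.118. Iron handling genes were lower in 3 of 10 cases, the ferric reductase Cybrd1 (-0.61 ± 0.16 [-0.54, -0.72]), Smad7 (-0.52 ± 0.13 [-0.40, -0.69]) and Id1 (-0.34 ± 0.11 [-0.14, -0.39]). Adjusted over the list alone 1 was higher and 5 lower, without a list call (camera adjusted p = 0.112). Lyz2 (0.75 ± 0.18 [0.93, 0.73]) and the mast cell receptor chain Fcer1a (0.79 ± 0.23 [0.40, 1.05]) rose.

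edgeR called 2481 genes at the high dose in duodenum over both sexes (16 against 15 libraries), 1330 higher and 1151 lower, with a median absolute log2 change of 0.36 and 67 over 1. The genes named as having the smallest p had edgeR adjusted p = 0.0104. Inside batch 1, 0 passed (506 at unadjusted p under 0.05) and inside batch 2 1184. Without male control replicate 1, whose markers resembled a more distal part of the small intestine, 1829 genes were called. The count was 1146 without female control replicate 1, 1334 without male high replicate 5, 0 with the ribosomal protein share as a covariate and 0 with 3 surrogate variables.

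**Figure D3:**
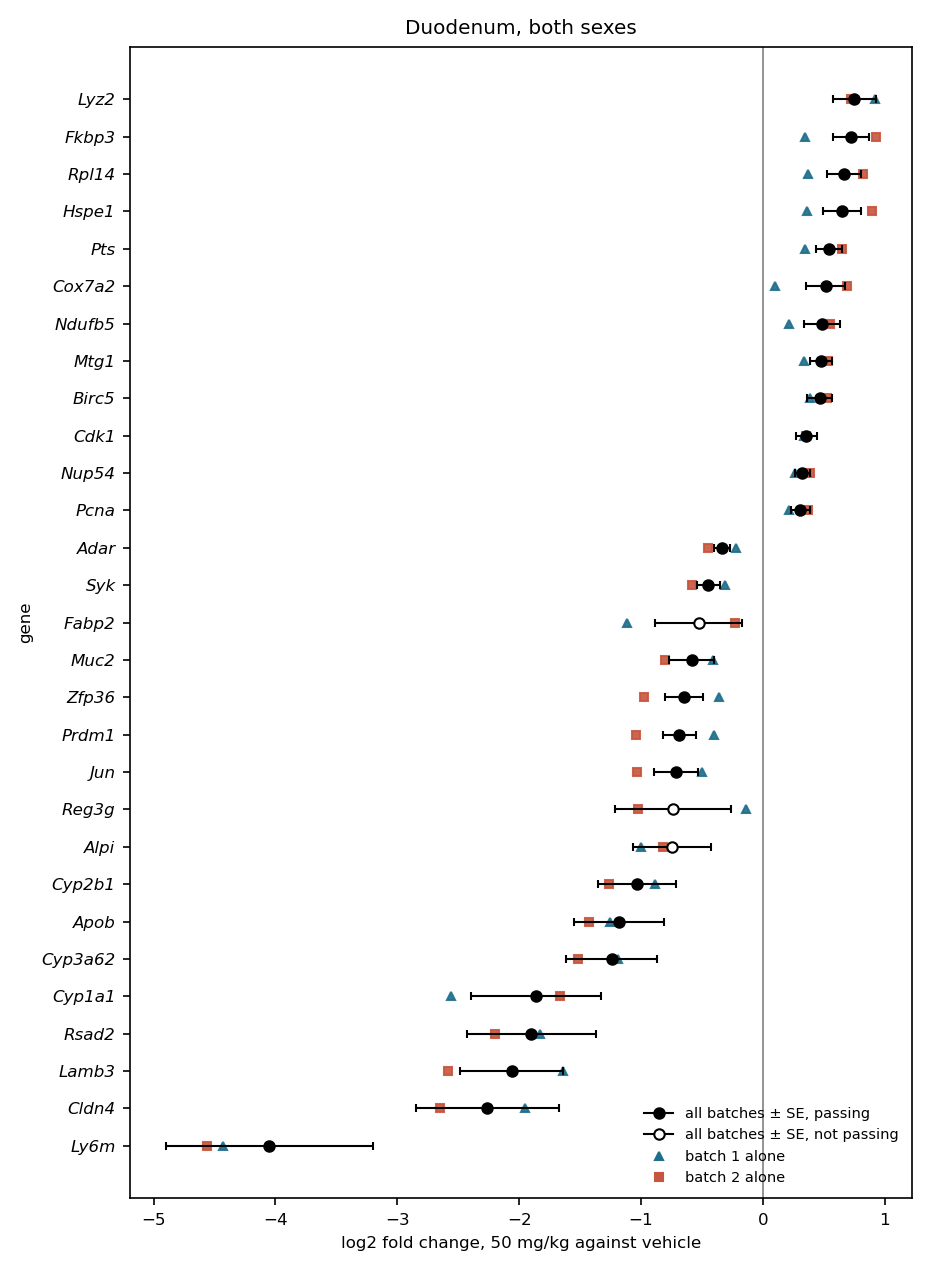
Log2 change ± SE at the high dose in duodenum (horizontal axis) for named genes, pooled (circles) and within batch 1 (triangles) and batch 2 (squares); open circles did not pass the edgeR threshold. Cyp1a1 stood at -1.86 ± 0.54 and Rpl14 at 0.67 ± 0.14.

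By sex, the duodenum had no gene past the threshold at the high dose with all libraries. In males edgeR called 0 (3650 at unadjusted p under 0.05; 1010 by DESeq2 and 0 by voom). Without male high replicate 6 it called 2164, without male control replicate 7 993 and without female low replicate 7 610. Among the closest were C1qtnf7 (1.1 ± 0.24 [1.60, 0.80]), Pts (0.69 ± 0.15 [0.51, 0.85]), and Tab2 (-0.33 ± 0.076 [-0.29, -0.40]), all at edgeR adjusted p = 0.0746, and Nts, a gene of the distal intestine, at 8.21 ± 18.6 to 0.646 ± 0.401 CPM with male control replicate 1 among the controls. In females it called 0 (2048 unadjusted; 3 by DESeq2 and 0 by voom). Lyz2 (1.18 ± 0.26 [1.30, 1.12]) and Tmem184b (-0.80 ± 0.20 [-0.56, -1.09]) were at edgeR adjusted p = 0.322. The test of sex by dose called 0 genes with edgeR (491 unadjusted), 0 with DESeq2 and 0 with voom. Ribosomal protein genes passed as a list in males (median 0.51, camera adjusted p = 3.97e-12, and 0.847 with an estimated correlation, 20 of 21 adjusted over the list alone and 0 over all genes). They also passed in females (0.40, adjusted p = 2.87e-11, and 0.818 with an estimated correlation, 15 adjusted over the list alone and 0 over all genes). High against low dose gave 0 genes by edgeR (1830 unadjusted), 1 by DESeq2 and 0 by voom.

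At the low dose the duodenum had higher cell cycle genes and lower immediate early genes as lists. Of 22 cell cycle genes 11 were higher adjusted over the list alone and 0 over all genes (median 0.21, camera adjusted p = 2.19e-10, and 0.329 with an estimated correlation). The helicase subunit Mcm5 (0.28 ± 0.072 [0.12, 0.43]) and Cdk1 (0.31 ± 0.087 [0.10, 0.44]) had the smallest p. Of 17 immediate early genes 8 were lower adjusted over the list alone and 0 over all genes (median -0.39, camera adjusted p = 1e-06, and 0.329 with an estimated correlation). Jun was at -0.67 ± 0.18 [-0.29, -1.21] and Zfp36 at -0.56 ± 0.16 [-0.16, -0.99]. Ribosomal protein genes (median 0.21, camera adjusted p = 1e-06) and cholesterol synthesis genes (0.15, 0.000639) were higher. Targets of CAR and PXR (-0.50, 0.00438), circadian genes (-0.18, 0.00286), MHC class II genes (-0.19, 0.00228) and enterocyte markers (-0.46, 0.0357) were lower. With an estimated correlation their adjusted p values were 0.715, 0.715, 0.673, 0.329, 0.673 and 0.809. Adjusted over the list alone these had 0, 0, 2, 2, 1 and 0 members past the threshold, and 0 over all genes. Cyp2b1 was at -1.08 ± 0.33 [-0.42, -1.99], Cyp3a62 at -1.1 ± 0.39 [-0.60, -2.16] and Cyp1a1 at -1.75 ± 0.55 [-1.32, -2.62]. Among the smallest p values were those of Hpdl (0.54 ± 0.11 [0.62, 0.53]), Ebna1bp2 (0.32 ± 0.072 [0.20, 0.41]), Tff1 (1.5 ± 1.01 to 0.445 ± 0.317 CPM) and the keratin Krt1 (1.11 ± 1.55 to 0.129 ± 0.234 CPM), at edgeR adjusted p from 0.159 to 0.199. edgeR called 0 genes (2132 at unadjusted p under 0.05; DESeq2 18, voom 3). It called 0 in males (1460 unadjusted; 13, 0) and 0 in females (1079 unadjusted; 2, 0). Inside batch 2 alone 252 passed, 222 of them lower, and 128 passed without female low replicate 7.

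In liver the camera test called cholesterol synthesis genes lower at the high dose over both sexes and in males. Of 23 such genes 22 had a negative change, with a median of -0.17 (camera adjusted p = 3.06e-08, and 0.876 with an estimated correlation). Over all genes or adjusted over the list alone, 0 members passed. Nsdhl, a sterol dehydrogenase, was at -0.14 ± 0.066 [-0.090, -0.14]. The median was -0.30 in males (camera adjusted p = 2.06e-11, and 0.798 with an estimated correlation) and -0.015 in females, where the list was not called (adjusted p = 0.797). The test of the difference between the sexes gave camera adjusted p = 2.16e-05, and 0.968 with an estimated correlation. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 0.021 ± 0.35 [-0.16, 0.10], Cyp1a1 at -0.20 ± 0.16 [-0.25, 0.046] and the CAR target Cyp2b1 at 0.46 ± 0.36 [-0.54, 0.34]. The NRF2 targets Hmox1 and Nqo1 were at -0.12 ± 0.16 [0.16, -0.39] and -0.19 ± 0.12 [-0.10, -0.26], and the metallothionein Mt1 at -0.19 ± 0.28 [-0.29, -0.55], none of these 6 passing (edgeR adjusted p = 1). Among the smallest p values were those of the growth factor Bmp4 (1.12 ± 0.26 [0.85, 0.96]), Mst1, a hepatic kringle protein (-0.54 ± 0.14 [-0.36, -0.44]) and Efcab2 (0.74 ± 0.21 [0.87, 0.67]), all at adjusted p = 1.

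At the low dose 4 gene lists went opposite ways in the sexes in liver. In males the nuclear respiratory chain genes had a median of -0.35 (camera adjusted p = 5.27e-09; 15 of 20 lower adjusted over the list alone), the ribosomal protein genes one of -0.52 (5.27e-09; 20 of 21) and the mitochondrially encoded genes one of 0.35 (0.000353; 6 of 13 higher). The NRF2 targets had one of -0.17 (0.0415; 0 of 18). All were at adjusted p = 0.888 with an estimated correlation, with 0 members past the threshold over all genes. In females the same lists were at 0.14, 0.33, -0.22 and 0.15 (adjusted p = 0.00439, 9.41e-07, 0.00867 and 0.0253, all at adjusted p = 0.798 with an estimated correlation), with 0 members past the threshold over all genes or adjusted over the list alone. The test of the difference between the sexes gave camera adjusted p = 2.45e-07, 2.45e-09, 0.000495 and 0.0179, each at adjusted p = 0.824 with an estimated correlation. Beside these lists, the ribosomal protein share was 2.03, 2.6 and 2.86% in male control replicates 3, 5 and 7 against 1.11 to 1.5% in the other male controls. It was 2.35, 2.6 and 3.56% in female low replicates 1, 2 and 6 against 1.2 to 1.94% in the others. Examples were Atp5po at -0.68 ± 0.20 [-0.18, -1.07] in males, Rps9 at -0.70 ± 0.22 [-0.19, -1.11] in males and 0.46 ± 0.22 [0.21, 0.72] in females, and Mt-cyb at 0.45 ± 0.14 [0.29, 0.54] in males and -0.30 ± 0.14 [-0.00425, -0.60] in females. Female livers also had higher interferon response genes as a list (median 0.40, camera adjusted p = 0.000116, and 0.798 with an estimated correlation), with the chemokine Cxcl10 at 1.35 ± 0.45 [0.27, 2.12] and 0 of 21 past the threshold or adjusted over the list alone. Male genes with the smallest p included Vamp3 (-0.52 ± 0.11 [-0.50, -0.64]), Srsf4 (0.60 ± 0.13 [0.29, 0.98]) and Atxn2 (0.57 ± 0.13 [0.32, 0.81]), at edgeR adjusted p = 0.0922.

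edgeR called no liver gene at either dose. The counts, with those at an unadjusted p under 0.05 and by the other tools, were 0 (272 unadjusted; DESeq2 0, voom 0) at the low dose over both sexes, 0 (3187 unadjusted; DESeq2 601, voom 574) in males and 0 (933 unadjusted; DESeq2 0, voom 0) in females. They were 0 (446 unadjusted; DESeq2 0, voom 0), 0 (639 unadjusted; DESeq2 0, voom 0) and 0 (200 unadjusted; DESeq2 0, voom 0) at the high dose. High against low dose gave 0 (609 unadjusted; DESeq2 0, voom 0), and the test of sex by dose 0 (3017 unadjusted; DESeq2 676, voom 531). Without male high replicate 6, the library with the largest ribosomal protein share of its group, 773 genes passed at the low dose in males and 424 in the test of sex by dose, which gave 408 without male high replicate 4.

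**Figure D4:**
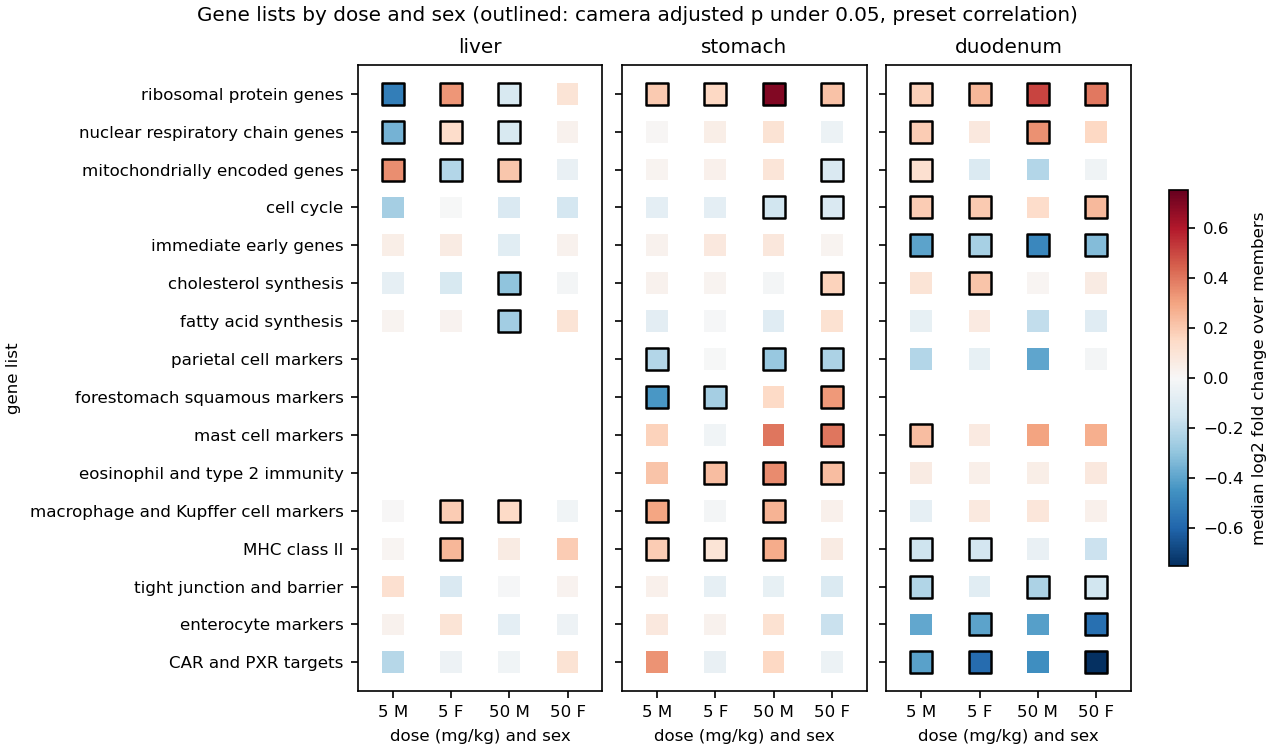
Median log2 change of 16 gene lists (rows) for each tissue, dose and sex (columns), on a colour scale centred at 0; outlined cells passed the camera test with a preset correlation (adjusted p under 0.05) and none passed with an estimated one. The ribosomal protein row was 0.70 in high-dose male stomach and -0.52 in low-dose male liver.

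Vehicle controls of the sexes differed in more genes in liver than in either gut tissue. Cyp2c11, a steroid hydroxylase of male rats, averaged 1520 ± 449 CPM (SD, n = 8) in males and 0.406 ± 0.462 CPM (n = 8) in females. In the same order Cyp2c13 averaged 1890 ± 717 and 1.66 ± 0.796 and the urinary protein Mup5 16900 ± 7270 and 2.14 ± 2.25. The oestrogen sulphotransferase Sult1e1 averaged 1450 ± 622 and 0.16 ± 0.144. Higher in females were Cyp2c12, a steroid hydroxylase of female rats (5.66 ± 0.45 [6.40, 5.49]), Cyp2c7 (1.93 ± 0.20 [2.15, 1.76]), the sulphotransferase Sult2a1 (2.15 ± 0.35 [2.64, 1.95]) and the transcription factor Cux2 (5.60 ± 0.35 [5.12, 6.17]). Members of the Cyp2c, Mup and sulphotransferase families resemble one another in sequence, so single levels are uncertain. Cyp2a2 stands for more than 1 gene identifier, with opposite directions, and is not read. edgeR called 2995 genes, 1384 higher and 1611 lower in females. The named ones had edgeR adjusted p = 7.42e-29 to 5.89e-06.

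In stomach and duodenum few genes differed between the control sexes, sex-linked genes among them. The Y-linked Ddx3y averaged 63.7 ± 8.02 CPM in male and 0.0134 ± 0.038 in female stomach. The X-linked Kdm6a was higher in females by 0.76 ± 0.065 [0.82, 0.73] in stomach and 0.81 ± 0.10 [0.70, 0.90] in duodenum, and Eif2s3 by 0.72 ± 0.090 [0.69, 0.77] and 0.64 ± 0.14 [0.82, 0.51]. Beyond these, female stomach had more Sectm1b (1.79 ± 0.37 [1.23, 2.45]). It had less of the transferrin receptor Tfrc (-0.97 ± 0.16 [-1.07, -0.92]) and elastin Eln (-0.75 ± 0.14 [-0.65, -0.92]). Female duodenum had less Igfbp3 (-0.87 ± 0.16 [-1.06, -0.82]) and the globin Hba-a2 (-1.88 ± 0.38 [-1.40, -2.65]). edgeR called 26 genes in stomach (12 higher and 14 lower in females, 23 and 7 inside batches 1 and 2). It called 12 in duodenum (3 and 9; 7 and 9), the named ones at adjusted p of 0.0415 or less.

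Duodenum of females carried more pancreatic acinar transcript over all doses. The acinar share was -2.09 ± 3.44 log2 percent (SD, n = 23) in females and -6.65 ± 3.4 (n = 24) in males. The difference was 4.72 within batch and dose [5.92, 4.36] (permutation p = 8e-05, adjusted p = 0.00336). Prss1 exceeded 100 CPM in 17 of 23 female and 7 of 24 male libraries. In liver the acinar share was 0.0199 ± 0.00987% (n = 22) in females and 9.376e-05 ± 6.283e-05% (n = 24) in males. There Cpa1 had medians of 131 CPM in females and 0 CPM in males, and Prss1 and Pnlip medians of 0 CPM in both.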

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

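The comparisons, their tests, the gene lists and the rule for naming genes were chosen before the data were examined. Of the tests in this part, those of the ribosomal protein share, the small noncoding RNA share, enterocyte markers, gene span, batches, a mixture of tissue, pancreatic tissue and other splits of the samples were chosen only after the result was seen. Pooled means over both sexes.

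The genes called at the high dose moved with the composition of the libraries. With the ribosomal protein share as a covariate 1 gene was called in stomach (680 without it, 0 shared) and 0 in duodenum (2481 without it), and the median absolute log2 change of the called genes went from 0.37 to 0.0811 in stomach (median SE 0.0982 and 0.0729) and from 0.36 to 0.052 in duodenum (0.106 and 0.0933), so the calls ended because the changes shrank and not because the errors grew. With the small noncoding RNA share 10 genes were called in stomach (9 shared, median 0.27) and 1607 in duodenum. With the enterocyte marker mean 2830 were called in duodenum (2138 shared). That mean was not shown to differ by dose, so this leaves fewer mature enterocytes open. As many genes as were called were also chosen inside 1 batch and read inside the other. At least 83% in duodenum and 69.3% in stomach kept their sign there. In each tissue 4 of 100 splits, the real one included, were as high (highest other 85.1 and 75.6). Permuted dose labels thus reached the real shares, so a difference between batches stays open in both tissues. Shorter genes had the higher changes (Spearman's rho over genes, which are not independent, -0.33 in stomach and -0.243 in duodenum). In size 6 and 33 of 100 splits matched this (highest other 0.379 and 0.42), so gene span cannot be told apart from chance. A shift of library composition may therefore underlie most of these calls, but the share itself rose with dose and tissue handling ran along with treatment, so an effect of the dose on ribosomal protein transcripts and an effect of handling or RNA quality both stay open.

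Duodenum male control replicate 1 stood apart from the other 46 duodenum libraries in markers of position along the gut. It was noticed by genes such as Fabp6, a bile acid binding protein of the ileum, at 3520 CPM against a median of 0.362, and among markers not looked at before the distal ones had a median log2 ratio to the other libraries of 5.04 and the proximal ones of -2.93, with Gata4 at 0.294 CPM against 155 and Cybrd1 (0.44) as an exception. A mixture with duodenum is argued against by Pdx1, at 0% of the other libraries' median of 49.6 CPM, where 3 counts would be 0.593%, and shallow sequencing by ranks of 18 of 47 in total count and 26 of 47 in genes detected, lowest first. The values are thus consistent with tissue of the distal small intestine, and whether another piece of gut was taken or the label is wrong stays open. No explanation by dose or sex was tested.

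Pancreatic acinar transcripts were higher in female than in male duodenum, by medians of 717 against 5.26 CPM for Prss1 and 206 against 1.96 for Pnlip. The 13 markers rose and fell together over the female libraries (median pairwise correlation 0.988), as pancreatic tissue in the pieces taken would give. A few libraries as the whole cause are argued against, since without the 4 female libraries with the most acinar counts the difference was 3.62 log2 units (permutation p = 0.001). Pancreas taken along with the gut may therefore be the source, more often in females, but why the sexes differed, through dissection or anatomy, was not tested. In stomach the list is less specific, with Clps at medians of 2160 CPM in females and 2380 CPM in males, over 100 CPM in 24 of 24 libraries of each sex.

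In 100 splits of the same libraries, the real one included, chance could be excluded for these counts of genes (splits with as many; real count against highest other; then splits with as many and highest other for 100 splits that also kept labels in their batch): in liver control sexes (1; 2995 against 111; 1, 1841); in stomach high dose pooled (1; 680 against 33; 1, 38), high dose in males (1; 1069 against 5; 1, 441), high against low dose (1; 107 against 7; 1, 83), control sexes (2; 26 against 89; 3, 80); in duodenum high dose pooled (1; 2481 against 8; 1, 846). By the count alone chance was left open for the control sexes in duodenum (8, 12 against 1294, then 6 and 4057), whose called genes had a median absolute log2 change of 4.42. Where the real count was 0 all 100 splits had as many, with highest others in liver 1 for low dose pooled, 1926 for high dose pooled, 4 for low dose in males, 2606 for high dose in males, 2 for low dose in females, 3 for high dose in females, 1628 for high against low dose, 2278 for sex by dose; in stomach 207 for low dose pooled, 2230 for low dose in males, 18 for low dose in females, 135 for high dose in females, 439 for sex by dose; in duodenum 39 for low dose pooled, 3769 for low dose in males, 2975 for high dose in males, 262 for low dose in females, 1 for high dose in females, 9 for high against low dose, 691 for sex by dose. By the number at an unadjusted p under 0.05, few splits had as many (then with labels kept in their batch): 1 (2) for low dose in males and 2 (3) for sex by dose in liver, and 3 (5) for high dose in males, 2 (3) in females and 6 (4) for low dose pooled in duodenum. The median of the other splits was 0 in every contrast, and where 1 called 3769 only 6 called any, so a few splits point to a structure of the samples that does not follow the groups. For lists with a preset correlation chance was left open for every count, also with labels kept in their batch (10 or more of 100 splits had as many). The counts were (splits with as many, then real against highest other, in the order low and high dose pooled, in males and in females) in liver 55 (5 against 16), 51 (6 against 12), 75 (4 against 14), 30 (7 against 12), 20 (9 against 15), 100 (0 against 12); in stomach 23 (10 against 18), 47 (8 against 16), 30 (9 against 20), 59 (7 against 20), 29 (9 against 16), 14 (11 against 15); in duodenum 44 (11 against 20), 95 (5 against 20), 19 (14 against 20), 98 (4 against 20), 44 (12 against 22), 58 (9 against 21).

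In 48 of 222 tests of a measure in a group, 1 library lay far from the others of its group by Dixon's criterion, where chance marks about 1 group in 20; the library is named by sex, dose and replicate and the range of the others of its group follows in brackets. Total counts were for liver 20700000 in male control 8 (9350000 to 12300000), 23700000 in female high 4 (9720000 to 10900000), for stomach 21100000 in female low 4 (6280000 to 10300000), 23900000 in female high 1 (6500000 to 14000000) and for duodenum 25500000 in male control 5 (8100000 to 10900000), 17900000 in male high 6 (9420000 to 11800000). The ribosomal RNA share in percent was for liver 0.0337 in male control 6 (0.00066 to 0.012), 0.0078 in female high 4 (0.000463 to 0.00185), for stomach 0.0036 in male control 3 (0.000164 to 0.00129), 0.00153 in male high 1 (0.00026 to 0.000631), 0.00212 in female low 4 (0.00033 to 0.00104), 0.00352 in female high 1 (0.000206 to 0.000996) and for duodenum 0.0547 in male control 8 (0.000963 to 0.00182), 0.00248 in male high 7 (0.000482 to 0.00143), 0.0237 in female control 7 (0.00141 to 0.00368), 0.0785 in female low 7 (0.000934 to 0.00378). The ribosomal protein share in percent was for liver 1.91 in male low 7 (1.05 to 1.19), 3.45 in male high 6 (1.01 to 1.96), 2.26 in female control 4 (1.11 to 1.64) and for stomach 4.39 in male control 8 (2.46 to 3.3), 6.9 in male low 7 (2.65 to 4.63), 7.19 in female control 2 (2.86 to 4.01). The small noncoding RNA share in percent was for liver 0.0189 in male low 7 (0.0049 to 0.00762), 0.0436 in male high 6 (0.00441 to 0.02), for stomach 0.0614 in female control 2 (0.00707 to 0.0174), 0.0716 in female high 2 (0.00562 to 0.0367) and for duodenum 0.046 in male control 2 (0.00669 to 0.0216), 0.0535 in male low 2 (0.00573 to 0.0191), 0.0448 in female control 2 (0.00687 to 0.0203). Cyp7a1 in log2 CPM was for liver 8.23 in male low 1 (5.31 to 6.51). Cyp1a1 in log2 CPM was for liver 1.1 in female low 8 (1.64 to 2.08). The mitochondrially encoded share in percent was for stomach 19.5 in male control 8 (10.8 to 13.5). The squamous marker share in percent was for stomach 3.04 in male control 6 (0.601 to 1.64), 2.87 in female high 1 (0.981 to 1.8). The acinar marker share in percent was for stomach 0.459 in male low 1 (0.188 to 0.304), 0.439 in male high 2 (0.182 to 0.287), 1.44 in female low 7 (0.191 to 0.479) and for duodenum 1.19 in male low 5 (5.66e-05 to 0.408), 0.416 in male high 6 (8.5e-05 to 0.0797), 6.46 in female control 4 (0.000283 to 0.71), 5.11 in female low 4 (0.00977 to 2.36). The striated muscle share in percent was for stomach 0.146 in male low 2 (0.00611 to 0.0443), 0.327 in female control 3 (0.00582 to 0.0534), 0.125 in female low 2 (0.00388 to 0.00827). Atp4a in log2 CPM was for stomach 11.40 in female high 5 (12 to 12.60). Alpi in log2 CPM was for duodenum 5.67 in male control 1 (8.82 to 11.20). The median correlation with the other libraries was for duodenum 0.928 in male high 5 (0.955 to 0.968), 0.905 in female low 7 (0.946 to 0.967).

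The change with dose differed between the sexes for 53 of 264 lists by camera with a preset correlation, 36 of them called in at least 1 sex and given here, and for 0 with an estimated one (adjusted p of the 36 from 0.218 to 0.968); the camera adjusted p of the difference is followed by the male and female median log2 changes. In liver at the low dose these were NRF2 oxidative stress targets 0.0179 (-0.17, 0.15), nuclear respiratory chain genes 2.45e-07 (-0.35, 0.14), mitochondrially encoded genes 0.000495 (0.35, -0.22) and ribosomal protein genes 2.45e-09 (-0.52, 0.33). In liver at the high dose these were cholesterol synthesis 2.16e-05 (-0.30, -0.015), fatty acid synthesis 0.00252 (-0.26, 0.10), macrophage and Kupffer cell markers 0.0239 (0.15, -0.028), nuclear respiratory chain genes 0.00913 (-0.12, 0.030), mitochondrially encoded genes 0.00913 (0.21, -0.057) and ribosomal protein genes 0.00252 (-0.12, 0.10). In stomach at the low dose these were macrophage and Kupffer cell markers 0.0125 (0.30, -0.017), smooth muscle markers 0.000377 (0.20, -0.018), enteric neuron and glia markers 0.0301 (0.26, 0.10), pancreatic acinar markers 1.42e-05 (0.033, 5.01), parietal cell markers 0.0223 (-0.22, -0.00183), forestomach squamous markers 0.0347 (-0.44, -0.25), unfolded protein response 0.0347 (-0.022, -0.13) and sex-linked genes 0.0223 (-0.038, 0.53). In stomach at the high dose these were cholesterol synthesis 0.0144 (-0.013, 0.17), macrophage and Kupffer cell markers 0.00165 (0.26, 0.037), Paneth and antimicrobial genes 0.00805 (0.98, -0.17), mitochondrially encoded genes 0.0111 (0.10, -0.12) and ribosomal protein genes 5.21e-12 (0.70, 0.22). In duodenum at the low dose these were interferon response 0.0256 (-0.17, 0.044), B and plasma cell markers 0.0189 (0.11, -0.94), mast cell markers 0.0256 (0.23, 0.069), pancreatic acinar markers 0.0179 (1.88, 1.75), gastric surface and neck mucous markers 0.00612 (-1.54, -0.92), Paneth and antimicrobial genes 0.012 (-0.57, 0.48), nuclear respiratory chain genes 0.0256 (0.19, 0.079) and mitochondrially encoded genes 0.00362 (0.12, -0.11). In duodenum at the high dose these were glucose metabolism 0.00897 (-0.052, -0.47), enterocyte markers 0.00205 (-0.41, -0.57), Paneth and antimicrobial genes 0.0338 (-0.30, 0.82), cell cycle 0.00166 (0.14, 0.24) and nuclear respiratory chain genes 5.41e-05 (0.34, 0.16). For the acinar list at the low dose in duodenum the test pointed to females although the male median was the higher, and acinar medians rest on genes near 0 CPM in many libraries.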

How the results depend on the processing

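Of the settings in this part, the ribosomal protein share, the small noncoding RNA share and the enterocyte marker mean as covariates, leaving out batch 3 and leaving out single libraries were chosen only after the results were seen. Of 209 gene results named, 151 passed the threshold and 42 kept their direction and their side of it under every setting run, out of 2466 gene results by setting. Counts of genes that stayed within 1.5 times under every setting other than single libraries were those of the control sexes in liver (2297 to 3959) and the counts of 0 for both doses over both sexes, the high dose in each sex and high against low dose in liver, and for the low dose in females and sex by dose in stomach. The test of sex by dose has no fit of only the groups compared, since it uses all groups. Genes under the filter were not tested, and at the smallest total of 4947800 counts low genes are read with less precision.

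Numbers of genes called changed as follows, with the number before in brackets. With DESeq2, calls were liver 601 for low dose in males (0), 676 for sex by dose (0), stomach 28 for low dose pooled (0), 1025 for high dose pooled (680), 3 for low dose in males (0), 1 for high dose in females (0), 318 for high against low dose (107), 59 for control sexes (26) and duodenum 18 for low dose pooled (0), 13 for low dose in males (0), 1010 for high dose in males (0), 2 for low dose in females (0), 3 for high dose in females (0), 1 for high against low dose (0). With voom, calls were liver 574 for low dose in males (0), 531 for sex by dose (0), stomach 1863 for high dose pooled (680), 9 for low dose in males (0), 438 for high against low dose (107), 128 for control sexes (26) and duodenum 3 for low dose pooled (0). With only the groups compared, calls were liver 1 for low dose in females (0), stomach 345 for high dose pooled (680), 337 for high dose in males (1069), 175 for high against low dose (107) and duodenum 7 for control sexes (12). Without batch 3, calls were liver 1 for sex by dose (0), stomach 0 for high against low dose (107) and duodenum 6 for low dose pooled (0). With 3 surrogate variables, calls were stomach 1 for low dose pooled (0), 0 for high dose pooled (680), 2 for low dose in males (0), 0 for high dose in males (1069), 0 for high against low dose (107), 45 for control sexes (26) and duodenum 0 for high dose pooled (2481), 40 for control sexes (12). With no filter on low counts, calls were stomach 420 for high dose pooled (680), 647 for high dose in males (1069) and duodenum 12 for low dose in males (0), 3 for high dose in males (0), 1 for high dose in females (0), 2 for sex by dose (0). With no batch term, calls were stomach 4 for high dose pooled (680), 3 for high dose in males (1069), 0 for high against low dose (107) and duodenum 1569 for high dose pooled (2481), 2 for low dose in males (0). With the ribosomal protein share, calls were stomach 1 for high dose pooled (680), 0 for high dose in males (1069), 351 for high against low dose (107) and duodenum 0 for high dose pooled (2481). With the small noncoding RNA share, calls were stomach 10 for high dose pooled (680), 3 for high dose in males (1069), 531 for high against low dose (107) and duodenum 1607 for high dose pooled (2481). With the enterocyte marker mean, calls were duodenum 939 for high dose in males (0). The fits of only the groups compared and without batch 3 use fewer samples; for the others the cause was not tested.

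Directions of called genes turned, in log2 change, with 3 surrogate variables for high dose pooled in stomach Dbi at -0.018 and Pigr at 0.048, for high dose in males in stomach Acacb at 0.00179, Hspe1 at -0.14, Ndufa4 at -0.10 and Atp5po at -0.053, for high dose pooled in duodenum Muc2 at 0.067, Cd3g at -0.084, Stmn2 at -0.036, Apob at 0.023, Clca4 at 0.12 and Ndufa4 at -0.012; with the ribosomal protein share for high dose in males in stomach Ccl2 at -0.12, Hspe1 at -0.29, Cox7a2 at -0.17, Ndufa4 at -0.19, Atp5po at -0.18 and Rpl4 at -0.018, for high dose pooled in duodenum Muc2 at 0.081, Gstp1 at -0.0012, Cd3g at -0.18, Stmn2 at -0.034, Sdf2l1 at -0.049, Cox7a2 at -0.00774 and Ndufa4 at -0.041. None of these passed the threshold after the turn, and the cause was not tested.

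Lists called numbered 140 over the 18 dose contrasts and 0 with an estimated correlation, where each of the 17 contrasts with a call went to 0. With 3 surrogate variables, list calls were liver 2 for high dose pooled (6), 4 for high dose in males (7), 4 for low dose in females (9), stomach 3 for high dose in females (11) and duodenum 6 for low dose pooled (11), 10 for high dose pooled (5), 10 for high dose in males (4). With the ribosomal protein share, list calls were liver 5 for low dose in females (9), 3 for high dose in females (0), stomach 4 for low dose in females (9) and duodenum 8 for high dose pooled (5), 10 for high dose in males (4), 5 for low dose in females (12). With no batch term, list calls were liver 3 for high dose in females (0). Without batch 3, list calls were liver 1 for high dose in females (0) and stomach 4 for high dose pooled (8), 3 for high dose in males (7). With the small noncoding RNA share, list calls were stomach 16 for high dose pooled (8), 13 for high dose in males (7). Without duodenum male control replicate 1, list calls were duodenum 12 for high dose pooled (5), 8 for high dose in males (4). With the enterocyte marker mean, list calls were duodenum 4 for high dose in females (9). The cause was not tested.

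Replicate numbers are shared between groups without a stated pairing. Libraries of 1 number had mean correlations of their deviations of -0.00324 in liver, 0.0341 in stomach and 0.018 in duodenum, over 0.1 in 40 of 110, 37 of 120 and 40 of 115 pairs, and 3 of 46, 15 of 48 and 8 of 47 libraries correlated best with one of their own number, where chance gives 5.75, 6 and 5.88. Not every pair was over 0.1, so the numbers were not taken as pairs. These deviations kept the differences between batches. In stomach, male and female libraries of the same dose and number mostly shared a batch. Shared batch and pairing thus cannot be told apart for the 15 in stomach. With the number as a replicate block, gene calls were stomach 1071 for high dose pooled (680), 226 for high against low dose (107), 56 for control sexes (26), list calls liver 1 for high dose in females (0); stomach 4 for high dose in males (7), and no other count moved by over 1.5 times.

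Leaving out each library of a tissue in turn changed a call or moved a count by over 1.5 times for the libraries named here by sex, dose and replicate, each followed by the count without it in brackets; the count with all libraries follows each comparison. In liver, low dose in males (0) ranged from 0 to 773, by male control 6 (1), male high 6 (773). High dose in males (0) ranged from 0 to 1, by male high 1 (1), 2 (1), 5 (1). Sex by dose (0) ranged from 0 to 424, by male high 4 (408), 6 (424). In stomach, low dose pooled (0) ranged from 0 to 1, by female control 5 (1). High dose pooled (680) ranged from 4 to 1465, by male high 4 (4), 3 (250), 2 (358), 6 (378), 7 (1170), female control 6 (131), 8 (313), 4 (351), 1 (395), 2 (1465), male control 4 (155), 2 (288), 6 (1231), female high 3 (211), 7 (246), 2 (349), 5 (1127). Low dose in males (0) ranged from 0 to 1, by male control 5 (1), 6 (1), male low 8 (1). High dose in males (1069) ranged from 275 to 1631, by male control 4 (275), 2 (508), male high 4 (287), 2 (329), 3 (357), 6 (547), 7 (1631). High against low dose (107) ranged from 10 to 421, by female high 1 (10), 7 (42), 3 (66), male high 4 (18), 3 (34), 1 (51), 6 (62), 2 (233), 7 (299), male low 3 (20), 2 (30), 7 (45), 1 (65), 4 (173), 8 (421), female low 3 (20), 4 (37), 2 (55), 5 (62), 8 (63), 6 (177), male control 6 (272). In duodenum, low dose pooled (0) ranged from 0 to 128, by male control 2 (1), male low 7 (1), female low 1 (1), 7 (128). High dose pooled (2481) ranged from 1146 to 3700, by female control 1 (1146), male high 5 (1334). Low dose in males (0) ranged from 0 to 7, by male control 8 (2), 3 (3), 2 (7). High dose in males (0) ranged from 0 to 2164, by female low 7 (610), male control 7 (993), male high 6 (2164). The other ranges were 2234 to 3330 for control sexes in liver, 19 to 36 for control sexes in stomach and 8 to 17 for control sexes in duodenum, and 0 to 0 for the rest. The cause was not tested.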

Other observations

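Of the tests in this part only the one with the ribosomal protein share was chosen after the result was seen. At the high dose in duodenum, lists without a call held single genes past the edgeR threshold. The chaperonin Hspe1 (0.65 ± 0.16 [0.37, 0.90]) and the endoplasmic reticulum proteins Sdf2l1 (0.41 ± 0.13 [0.33, 0.57]) and Creld2 (0.27 ± 0.095 [0.17, 0.46]) were higher, while the stress chaperones Hspa1a (-0.77 ± 0.27 [-0.23, -0.99]) and Bag3 (-0.50 ± 0.11 [-0.17, -0.70]) were lower. The lipid droplet genes Plin2 (-0.63 ± 0.23 [-0.83, -0.56]) and Cidec (-0.71 ± 0.24 [-0.84, -0.72]), the lipid regulator Srebf1 (-0.25 ± 0.076 [-0.19, -0.33]) and the NRF2 target Osgin1 (-0.41 ± 0.11 [-0.21, -0.45]) were lower, and Gstp1 was higher (0.32 ± 0.11 [0.29, 0.41]). The MHC class II regulator Ciita (-0.36 ± 0.12 [-0.084, -0.56]) and the invariant chain Cd74 (-0.31 ± 0.11 [-0.067, -0.32]) were lower, and the T cell gene Cd3g (0.80 ± 0.29 [0.37, 1.23]), the plasma cell gene Mzb1 (0.51 ± 0.17 [0.33, 0.56]) and the neuronal gene Stmn2 (0.35 ± 0.11 [0.31, 0.40]) higher. With the ribosomal protein share as a covariate Sdf2l1, Gstp1, Cd3g and Stmn2 turned negative without passing. All named here were at edgeR adjusted p from 0.0104 to 0.0495.

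The labels number the libraries alike in the 3 tissues, and libraries of 1 number could come from the same animal. If they did, their deviations from the group means would correlate across tissues and their best match would often be their own number. The mean correlations were 0.0252 (liver and stomach), 0.022 (liver and duodenum) and 0.0381 (stomach and duodenum), and 162, 262 and 95 of 1000 permutations of the numbers within groups gave as high a mean. The best match was the own number in 8, 4 and 10 cases, where chance gives 6. The data gave no sign that the numbers follow animals, and low correlations between tissues of 1 animal would look the same.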
